A study of Homo sapiens with 8 samples.

How the data were processed

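Gene expression was measured on 8 Agilent two-colour arrays carrying 41000 distinct probes for human transcripts. The cells were SK-Mel-28 and LOX, a pair of established human melanoma lines, each carrying a tetracycline-inducible microRNA directed either at TR1 or at a control. Per the labels' protocols, cells grew for 72 h with or without 1 µg/ml tetracycline, which switches the microRNA on, before total RNA was taken. Each line gave 1 array in each of 4 conditions (control miRNA uninduced, control miRNA induced, TR1 miRNA uninduced, TR1 miRNA induced), so each condition had n = 2 arrays, 1 per line. Per the labels, Cy5 held the RNA of the named condition and Cy3 held control RNA of the same line on every array. Dyes were not swapped, so a dye effect common to the arrays cancels only in differences between arrays.

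Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.5.1.1, and probe positions are on the human build hg18. The deposited intensity values comprise the mean brightness of each spot and the median of its local background in both dyes. The deposited intensity values also include processed signals, which that software had background-subtracted, detrended and dye-normalized with LOWESS, per the file headers. The deposited log10 ratios are Cy5 over Cy3 of those processed signals, per the file headers. The deposited p-values test the log ratio of each spot under that software's error model, per the file headers, and they entered no comparison between conditions. The authors' deposited table of the whole series holds log2 ratios, and its values equalled the log10 ratios converted to log2 within 0.0001 at 100% of spots on each array. The median of every column of that table was 0. Its scale and direction were settled by this match. How it was made is not given in the sources used here.

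The main values were recomputed from the spot means and backgrounds in limma 3.58.1 (R 4.3.3): normexp background correction with an offset of 50, then loess within each array, with the 1639 control features among the 45015 features given weight 0 and then left out. Spots that the software had marked as outliers, 69 to 151 per array, were removed, and no spot was saturated. Replicate spots of a probe were averaged. A probe entered when Cy5 was well above background in both lines in at least 1 condition, which 26923 probes met; 63 of these were left out for an outlier spot. Each gene was represented by its probe of highest mean brightness, and 5401 genes had over 1 such probe. Probes were named through RefSeq accessions (25398 probes), current symbols (2510) or older symbols (789), and 12303 probes kept the name the array gives them. The resulting 19555 genes were tested.

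All 8 arrays entered a single limma fit of log2(Cy5/Cy3) on the 4 conditions with the cell line as a block, tested two-sided with eBayes (residual degrees of freedom 3, prior degrees of freedom 4.819) and Benjamini-Hochberg adjustment over genes at 0.05. Same-numbered samples of the conditions are of the same cell line, hybridised on the same slide against the same reference, which is why the line was the block. The correlation of array deviations from their condition means within a line lay between 0.0928 and 0.851 over 6 pairs of conditions. Line, slide and reference RNA cannot be told apart. Conditions were compared within a slide, and values within each line stand beside the means. The 5 comparisons were induced TR1 against induced control miRNA, which was the main one, uninduced TR1 against uninduced control miRNA, tetracycline against none in control miRNA cells and in TR1 miRNA cells, and the difference of those tetracycline changes. Errors are the standard errors of the fit. Where a probe was not well above background on any array of a condition, only a bound is given. It sets the bright condition's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal, in normalized Cy5 values, and it is open to dye bias.

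The 29 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. They covered NRF2 targets, the thioredoxin, glutathione, selenoprotein, pentose phosphate, glycolysis, hypoxia, oxidative phosphorylation, mitochondrial ribosome, ATF4, heat shock, metallothionein, p53, cell cycle, apoptosis, interferon, NF-kB, cholesterol, iron, antioxidant, ribosomal protein and miRNA processing systems, melanocyte, dedifferentiated melanoma and adhesion genes, and markers of keratinocytes, fibroblasts, blood and endothelium. TXNRD1 and TXN were left out of the lists. An estimated correlation and fry were the alternatives for the list test. A list's median within a line was placed among 10000 random lists of the same size and brightness, as a description. The named genes were TXNRD1 and TXN, then the genes of largest change past the threshold with the same sign in both lines, 10 higher and 10 lower for the main comparison and 5 and 5 for the others. Empty places went to genes of smallest p with a change of at least 0.58 (log2), which missed the threshold. From each list came at most 4 members past the threshold or, with none, at most 2 of largest change with the same sign in both lines. The groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined, except for a fit of the 4 TR1 miRNA arrays alone, which was added after seeing the data. Alternatives changed the background correction, normalization, filter, outlier spots, probe choice, block, spread model, value table and list test, and left out each array in turn.

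The fit was tested on simulated data for the main comparison, with some of the 19555 genes changed. Of 50 genes changed by 0.58 (log2), 32 were called (64%), and of 50 genes each changed by 1, 2 or 3, all 50 were called. In the same data 12 of 19355 unchanged genes were called, 6.19% of the calls. With no gene changed, 1 gene and 0 of 29 lists were called by limma and camera. The simulated spread of each gene was the fitted one, which eBayes had already drawn towards a common value. The shares of changed genes called can therefore exceed those for real changes of the same size. The simulated genes also varied independently of each other. The list result therefore cannot show how often camera calls lists whose members vary together. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.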

Results

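Total RNA from SK-Mel-28 and LOX, a pair of human melanoma cell lines, was profiled on 8 two-colour arrays. Both lines carried a tetracycline-inducible microRNA directed either at TR1 or at a control, and each was grown for 72 h with 1 µg/ml tetracycline (induced) or without it (uninduced). The 4 conditions had n = 2 arrays each, 1 from each line, and every value is a log2 ratio of the condition over control RNA of the same line. Between 28484 and 30983 spots per array were well above background in the channel holding the condition's RNA (65.7% to 71.4% of spots). The number of arrays limits the precision. Nothing in the labels describes repeat cultures of a line, so p-values of single genes do not measure the spread between such cultures. They rest on the spread between the 2 lines, pooled over the 4 conditions and drawn by eBayes towards that of all genes. The list p-values with the preset correlation set a list's members against the other genes, treated as nearly independent. They do not measure agreement between the lines, and a list can pass where the lines differ. The series design names the direct comparison of the induced TR1 miRNA with the induced control miRNA, with the uninduced situation evaluated beside it.

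The short name TR1 is used for thioredoxin reductase 1 (TXNRD1), the selenoenzyme that keeps cytosolic thioredoxin reduced, while the series title calls the target thioredoxin 1, which is the gene TXN. Both transcripts were therefore examined first. TXNRD1 was lower in TR1 miRNA cells of both lines, more so with tetracycline, and TXN was not. The TXNRD1 probe (A_23_P204581, chromosome 12, 103266763 to 103266822, hg18) fell by 2.73 on the log2 scale in induced TR1 miRNA cells against induced control miRNA cells (SE 0.146, n = 2 lines), 6.63-fold lower on average (limma adjusted p = 0.00176). It was 14.4% of the control level in SK-Mel-28 and 15.8% in LOX. Without tetracycline the difference was -1.39 ± 0.146 (SE), with 31.04% of the control level in SK-Mel-28 and 46.6% in LOX. Its adjusted p was 0.0534 over all genes and 2.77e-05 over TXNRD1 and TXN alone. Tetracycline gave a change of -1.32 ± 0.146 (SE) in TR1 miRNA cells (adjusted p 0.132 over all genes, 4.06e-05 over the 2 genes) and of 0.01 ± 0.146 (SE) in control miRNA cells. The latter was -0.01 with median centring, -0.00141 with Cy5 alone, -0.09 without the SK-Mel-28 induced control array, -0.13 without the LOX uninduced control array and 0.15 without the SK-Mel-28 uninduced control array. With the processed signals or the deposited table the change in TR1 miRNA cells was -2.01, and the difference of the changes given below was -2.03. The uninduced difference passed over all genes with no filter on dim probes (adjusted p 0.0256), an intensity trend (0.0385), without the LOX uninduced TR1 array (-1.65, 0.0222) or without either induced TR1 array (0.0488 each). The tetracycline change in TR1 miRNA cells minus that in control miRNA cells was -1.33 ± 0.206 (SE), with adjusted p values of 1.00 over all genes and 0.000432 over the 2 genes.

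TXN, measured by 2 probes, was higher by 0.35 ± 0.115 (SE) after induction of the TR1 miRNA than after that of the control miRNA, with an adjusted p of 0.576 over all genes and 0.0178 over the 2 genes. Its difference between uninduced cells was -0.10 ± 0.115 (SE), and it was positive, 0.13, with median centring, which put the median of all genes at 0.103 in the induced and 0.109 in the uninduced comparison. The second TXN probe differed by 0.02 between uninduced cells in the loess-normalized values. The induced TXN difference was 0.66 with median centring and 0.20 without the LOX induced control array, and the uninduced one was -0.17 without the LOX uninduced TR1 array. In TR1 miRNA cells TXN differed by 0.33 with tetracycline (adjusted p 1.00 over all genes, 0.0218 over the 2 genes), and in control miRNA cells by -0.11, or 0.03 without the LOX and -0.26 without the SK-Mel-28 induced control array. The mitochondrial paralog TXNRD2 differed by 0.23 on its brighter probe and TXNRD3 by -0.12 in the main comparison, with unadjusted limma p values of 0.105 and 0.372. The TXNRD1 call of the main comparison ended with the software's processed signals (-3.65, adjusted p 0.148), the deposited log2 table (-3.65, 0.147) and a normexp offset of 0 (-3.24, 0.0767). It also ended without the SK-Mel-28 or the LOX array of the induced control miRNA (-2.63, adjusted p 0.0865, and -2.83, 0.0519), and over all 19 alternatives the change lay between -3.65 and -2.63.

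**Figure D1:**
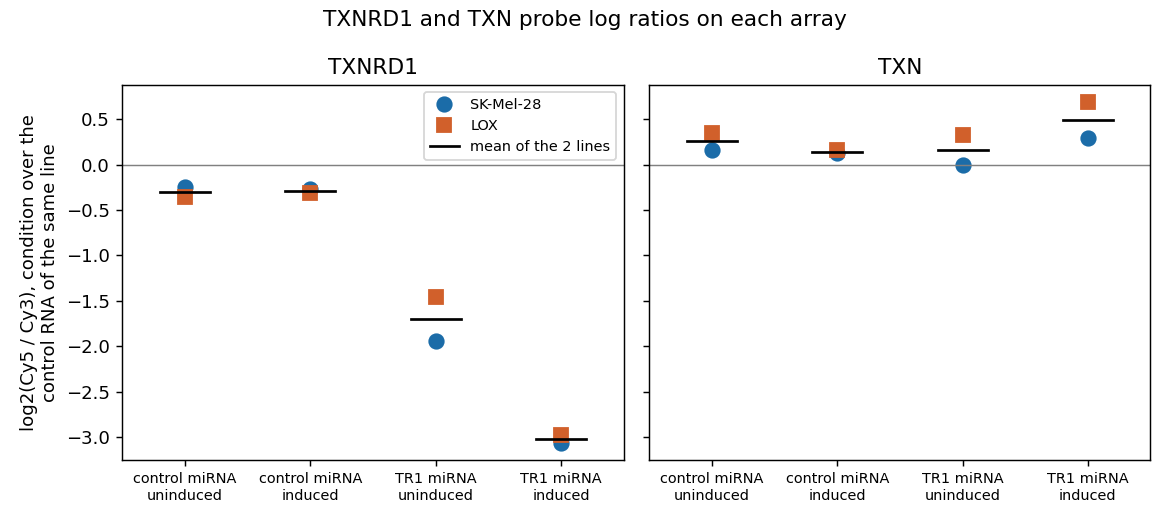
Log2 ratios of the TXNRD1 probe (left) and the brighter TXN probe (right) on each of the 8 arrays, by condition, with circles for SK-Mel-28, squares for LOX and bars for the mean of both lines. TXNRD1 lay at -0.25 to -0.35 in control miRNA cells, at -1.94 and -1.46 in uninduced TR1 miRNA cells and at -3.06 and -2.98 in induced TR1 miRNA cells.

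In the main comparison, TXNRD1 fell in induced TR1 miRNA cells, the only gene named by rank that passed the threshold, and no gene rose past it. Genes of the NRF2 response, which raises antioxidant and detoxifying enzymes under oxidative stress, were among the highest ranked on the higher side. NQO1, a quinone reductase, differed by 0.81 ± 0.103 (SE, 1.75-fold), and SLC7A11, the cystine importer that feeds glutathione synthesis, by 1.17 ± 0.207 (2.25-fold). On the lower side stood TXNIP, the thioredoxin-binding protein (-0.63), the collagen COL18A1 (-0.85), the basement membrane proteoglycan agrin (AGRN, -0.66) and the collagen chaperone FKBP10 (-0.63). Of 19555 genes, 6 passed, all lower. Beside TXNRD1 they held BG001037 (-1.68 ± 0.137, adjusted p 0.01004), a transcript whose probe overlaps the TXNRD1 probe on the opposite strand (chromosome 12, 103266725 to 103266784). The others were the unnamed probe A_24_P597242 (chromosome 10, 85755915 to 85755974; adjusted p 0.0496), which was not well above background on any TR1 miRNA array, and 3 probes without a genome position. These 5 fall outside the rule for named genes and were chosen after their values were seen.

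The other genes named by rank missed the threshold, with adjusted p values from 0.0778 to 0.312. On the higher side they were AAR2 (0.80), TRIM16L (0.97), CADPS (0.68), SNRPG (0.66), ASB3 (0.86), ACAP2 (0.90), CDC42SE2 (0.70) and the helicase gene HELB (0.64). For CDC42SE2, 3 other probes had the opposite sign. On the lower side they were the actin-binding COTL1 (-0.76), MREG, a gene of melanosome transport (-0.73), MMD (-0.90), STMN3 (-0.94) and FRMD8 (-0.70). With the mean of all probes CDC42SE2 was at 0.08, COL18A1 at -0.50 and STMN3 at -0.62. COTL1 was at -0.45 and FKBP10 at -0.39 with median centring, and CADPS at 1.11 and HELB at 1.04 with the processed signals or the deposited table. At an unadjusted p under 0.05 there were 743 genes higher and 905 lower, 8.43% of the genes tested. Across genes, which are not independent replicates, the SK-Mel-28 and LOX differences had a Pearson r of 0.240 and a Spearman rho of 0.161, and 55.4% of genes had the same sign. The count of 6 was 0 with a normexp offset of 0, 1 with the processed signals, the deposited table or probes bright on all 8 arrays, 2 without the line as a block and 10 with Cy5 alone. It was 0 without the SK-Mel-28 induced control array and 1 without the LOX induced control array.

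A set of probes set the control miRNA cultures apart from the TR1 miRNA cultures in both lines. Of 41000 probes, 12 were well above background on the 4 control miRNA arrays and on no TR1 miRNA array, and 7 of the 12 belonged to the 416 probes without a position in the human genome. This pattern was looked for only after the called probes were seen, which are among those counted, so no test of it is given. The reverse pattern was met by 7 probes, 0 of them without a position. With n = 2 lines per condition, the probe with the largest bound, A_24_P938342, was at least 62.3-fold lower in uninduced (adjusted p 0.0170) and at least 74.8-fold lower in induced TR1 miRNA cells (adjusted p 0.00672). A_23_P113952 was at least 45.6-fold (0.0255) and at least 54.1-fold lower (0.01004), and A_24_P920715 at least 5.53-fold (0.0163) and at least 5.21-fold lower (0.00514). The other 4 missed the threshold. This signal moves with every difference between TR1 and control miRNA cells, and it was not well above background on the 4 arrays compared for tetracycline in TR1 miRNA cells.

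**Figure D2:**
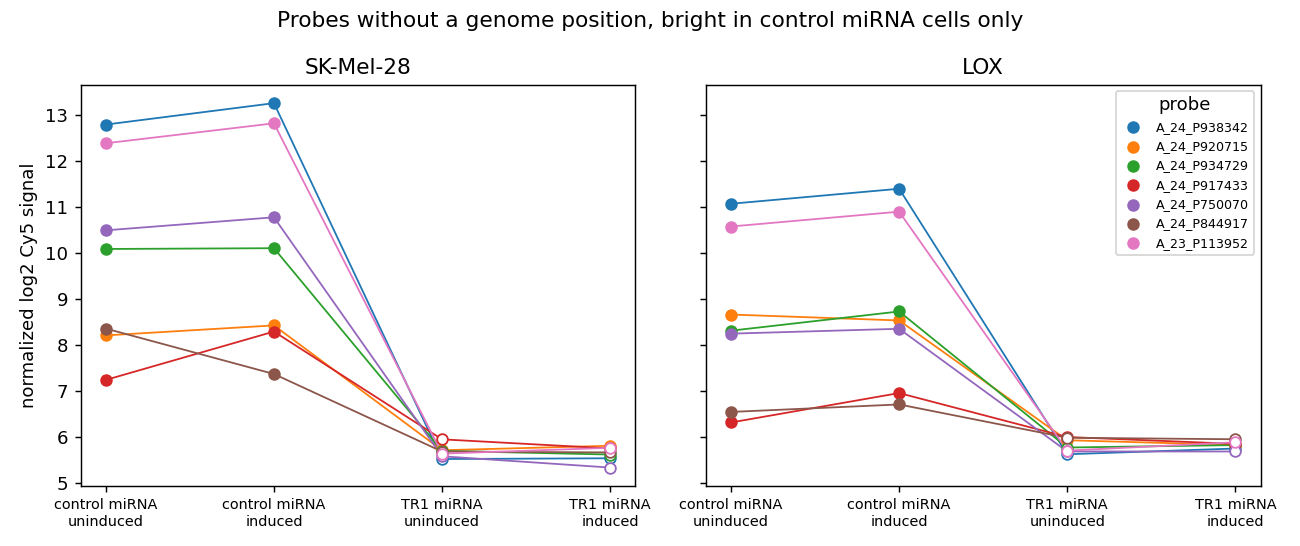
Normalized log2 Cy5 signal of the 7 probes without a human genome position, by condition, in SK-Mel-28 (left) and LOX (right), 1 line per probe, with filled points for spots well above background and open points for spots that were not. All 7 were well above background on the 4 control miRNA arrays and on none of the 4 TR1 miRNA arrays.

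The list tests found 11 of 29 lists past 0.05 in the main comparison with the preset correlation. No list passed (0 of 29) with an estimated correlation in camera or with fry, where the unadjusted p of NRF2 targets was 0.0139 and 0.00920. NRF2 targets rose together (median log2 change 0.17, 18 of 32 members higher and 2 lower in both lines, adjusted p = 3.71e-08). That adjusted p was 0.389 with an estimated correlation, as it was for each of the other 5 lists that rose. No member passed over all genes, and 5 did when adjusted over the list alone: SLC7A11, NQO1, PGD, GSR and EPHX1. The glutathione system rose (median 0.07, adjusted p = 0.0177), with 2 of 25 members past the test adjusted over the list alone, SLC7A11 and glutathione reductase (GSR, 0.53, whose second probe had the opposite sign). The pentose phosphate and NADPH supply list rose (median 0.11, adjusted p = 0.0391), with PGD at 0.63 and RPIA at -0.46 past the test adjusted over the list alone. Cholesterol synthesis genes were higher in induced TR1 than in induced control miRNA cells (median 0.41, 24 of 29 members higher in both lines, none lower, adjusted p = 1.26e-10). Their median was 0.16 without the SK-Mel-28 induced control array (adjusted p 0.0119) and 0.62 without the LOX induced control array. The sterol sensor INSIG1 was at 1.04 and the oxidase MSMO1 at 0.84, and no member passed when adjusted over the list alone. The cholesterol list did not rise with tetracycline within TR1 miRNA cells, where its median was -0.14. It fell with tetracycline in SK-Mel-28 control miRNA cells (median -0.87), and in LOX it was already higher between uninduced cells (median 0.40). Cytosolic ribosomal proteins (median 0.15, adjusted p = 8.50e-05; RPL8 0.31) and cell cycle genes (median 0.08, 24 of 48 higher in both lines, adjusted p = 0.00547; CENPA 0.49, KIF11 0.36) rose as lists with 0 members past either adjustment by limma. MSMO1 was at 0.37 without the SK-Mel-28 and 1.32 without the LOX induced control array, and INSIG1 at 0.68 without the LOX induced TR1 array. With the mean of all probes GSR was at 0.23 and KIF11 at 0.22. With median centring RPIA was at -0.27, KIF11 at 0.54 and RPL8 at 0.63, and RPL8 was at 0.15 with Cy5 alone.

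The lists that fell in induced TR1 miRNA cells covered inflammation, p53, hypoxia, invasion and matrix. NF-kB and inflammatory mediators fell (median -0.45, adjusted p = 5.97e-06, 0.389 with an estimated correlation), with a median of -0.76 in SK-Mel-28 and -0.01 in LOX. The chemokine CXCL1 was at -4.09 in SK-Mel-28 and -0.38 in LOX, and the apoptosis inhibitor BIRC3 at -2.40 and -0.18. The NF-kB list was already lower between uninduced cells (median -0.40), and with tetracycline in TR1 miRNA cells its median was 0.07. p53 targets fell (median -0.16, adjusted p = 0.00547, 0.656 with an estimated correlation), with a median of -0.40 in LOX and 0.03 in SK-Mel-28. BAX was at -0.53 (1 of its 2 other probes had the opposite sign) and PLK3 at -0.46. Hypoxia and HIF1 targets fell (median -0.13, and -0.13 in each line, adjusted p = 0.00668, 0.436 with an estimated correlation), with ANGPTL4, a lipoprotein lipase inhibitor, at -0.99 and past the test adjusted over the list alone. Adhesion and matrix genes fell (median -0.13, adjusted p = 0.0268, 0.389 with an estimated correlation). Adjusted over the list alone, 3 members passed, ITGB1 (-0.66) and ITGA6 (-0.54), which are integrins, and COL6A1 (-0.65). Genes of dedifferentiated or invasive melanoma fell (median -0.17, adjusted p = 0.0164, 0.389 with an estimated correlation), with tenascin C (TNC) and fibronectin (FN1) both at -0.61. Without the SK-Mel-28 induced TR1 array CXCL1 was at -0.90 and BIRC3 at -0.51, and without the LOX one at -3.57 and -2.07. Median centring put PLK3 at -0.29, ITGB1 at -0.36 and TNC at -0.38. BAX was at -0.28 without the LOX induced control array, and ANGPTL4 at -1.68 with the processed signals or the deposited table.

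The other 18 lists did not pass. Their adjusted p values were 0.0619 for the mitochondrial ribosome, 0.118 for melanocyte differentiation (median 0.06), 0.135 for apoptosis regulators, 0.169 for other antioxidant enzymes and 0.178 each for the ATF4, heat shock and interferon lists. They were 0.307 each for metallothioneins and keratinocyte markers, and 0.319 for the thioredoxin and peroxiredoxin system, in which TXNIP passed when adjusted over the list alone. In the ATF4 list 4 members passed when adjusted over the list alone, SLC7A11, PCK2 (0.56), PDIA4 (-0.45) and EDEM1 (-0.47), and in the antioxidant list 2, NQO1 and PON2 (-0.38). In the apoptosis, iron and endothelial lists 1 each did, BIRC2 (-0.54), SLC7A11 and ROBO4 (-0.70). The remaining adjusted p values were 0.361 for iron handling, 0.482 for oxidative phosphorylation, 0.495 for glycolysis, 0.557 for endothelial, 0.575 for fibroblast and 0.615 for blood cell markers, 0.575 for miRNA processing and 0.950 for selenoproteins. Without the SK-Mel-28 array of the induced control miRNA 6 lists passed, and 7 of the 11 calls ended (adjusted p 0.130 to 0.531), those of the pentose phosphate, hypoxia (median -0.08), cell cycle, NF-kB (-0.12), invasive melanoma (-0.01), adhesion (-0.02) and ribosomal (0.04) lists. The p53 median was -0.32 there. Without the LOX array of the induced TR1 miRNA, 4 ended (0.0593 to 0.897), those of pentose phosphate (median 0.04), hypoxia, p53 (-0.05) and cell cycle, while NF-kB was at -0.72 and invasive melanoma at -0.11. Without the LOX array of the induced control miRNA 2 ended (glutathione, median 0.12, and p53, with adjusted p values of 0.0810 and 0.778), and NF-kB was at -0.69. The adhesion call also ended without 3 other arrays, SK-Mel-28 uninduced control, SK-Mel-28 induced TR1 and LOX uninduced control (0.0588 to 0.0768). Without the SK-Mel-28 induced TR1 array the medians were -0.305 for p53 targets, -0.24 for NF-kB, -0.10 for invasive melanoma and 0.10 for ribosomal proteins.

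**Figure D3:**
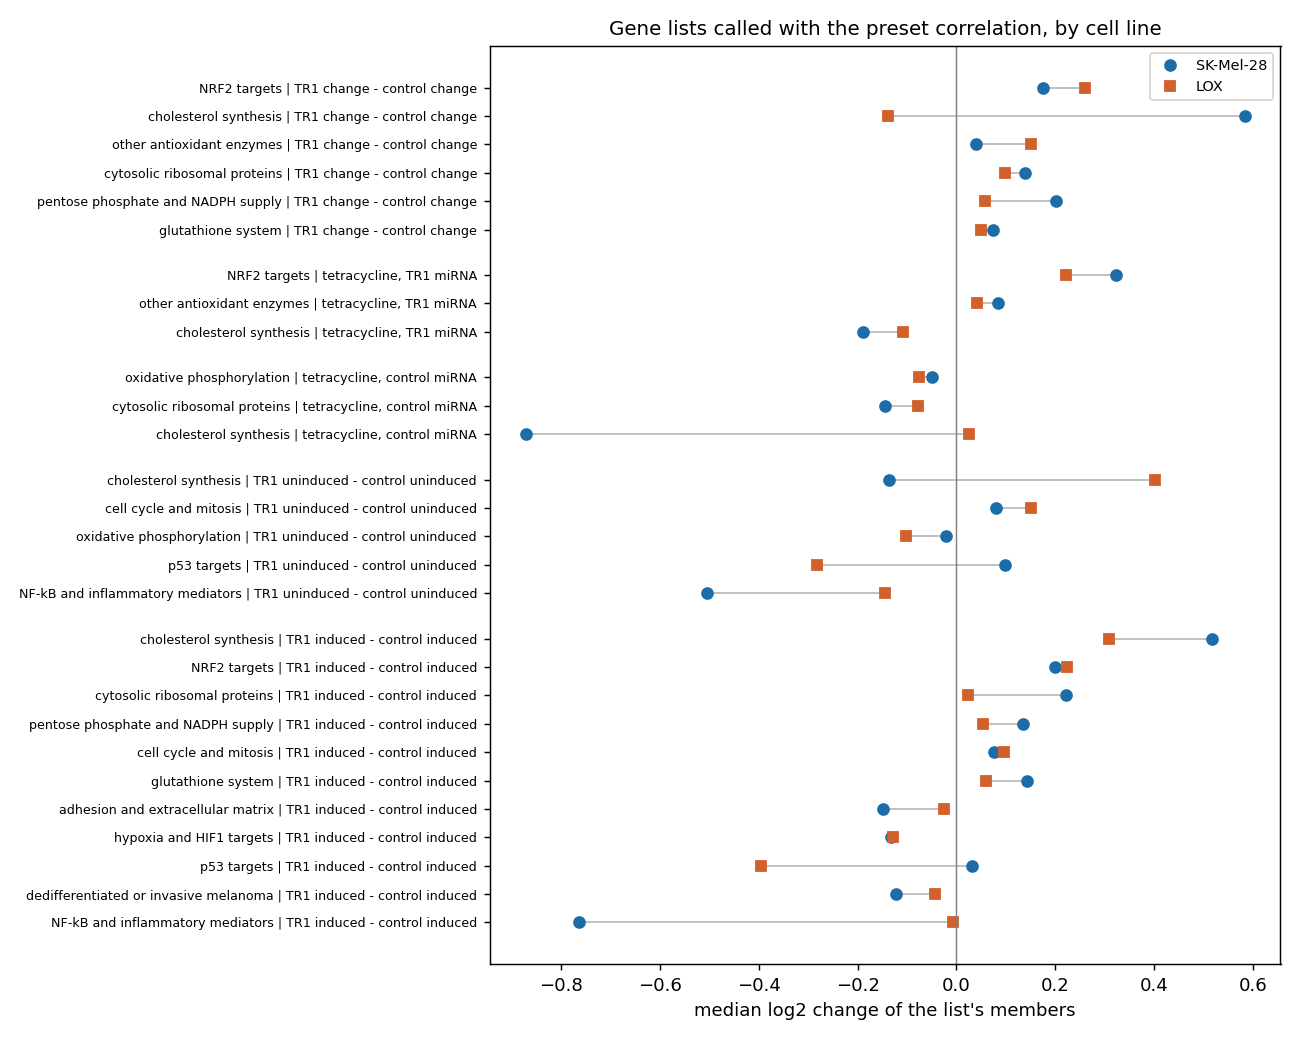
Median log2 change of each gene list called with the preset correlation, by comparison, with circles for SK-Mel-28 and squares for LOX joined by a line. NRF2 targets lay above 0 in both lines in each comparison that involved induction of the TR1 miRNA, and these comparisons share the induced TR1 arrays. Between uninduced cells NRF2 targets did not pass and are not drawn. Cholesterol synthesis genes lay at -0.87 in SK-Mel-28 and 0.02 in LOX for tetracycline in control miRNA cells.

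Before induction, TR1 miRNA cells already had less TXNRD1 than control miRNA cells (above), and the lists that moved were cell cycle genes, cholesterol synthesis, inflammation, p53 targets and oxidative phosphorylation. Cell cycle genes rose (median 0.11, 35 of 48 higher and 1 lower in both lines, adjusted p = 6.22e-07, 0.827 with an estimated correlation), with thymidylate synthase (TYMS) at 0.40 and E2F2 at 0.32, for which 1 other probe had the opposite sign. NF-kB and inflammatory mediators fell (median -0.40, adjusted p = 2.51e-05, 0.827 with an estimated correlation), with CXCL1 at -4.12 in SK-Mel-28 and -0.40 in LOX, and CXCL2 at -2.15 and -0.27. Cholesterol synthesis genes rose as a list (median 0.11, adjusted p = 0.00795, 0.886 with an estimated correlation), with medians of -0.14 in SK-Mel-28 and 0.40 in LOX. SCD, the stearoyl-CoA desaturase (0.72), passed when adjusted over the list alone, while MVK was at 0.33 (-0.00309 without the LOX uninduced control array). NRF2 targets did not pass between uninduced cells (median -0.05, -0.06 in SK-Mel-28 and -0.04 in LOX, adjusted p 0.606). In lists that did not pass, TXNIP (-0.55), ITGB1 (-0.52), NUAK1 (0.52), ISG20 (-1.07) and ROBO4 (-0.66) passed when adjusted over their list alone. Oxidative phosphorylation fell (median -0.07, adjusted p = 0.0422, 0.827 with an estimated correlation, with NDUFB8 at -0.32 and NDUFB3 at -0.16). With median centring its median was 0.14 and NDUFB3 was at 0.04, where the median of all genes was 0.109. p53 targets fell (median -0.10, adjusted p = 0.0422, 0.886 with an estimated correlation), with RPS27L at -0.34 and TP53INP1 at 0.36 (-0.08 without the SK-Mel-28 uninduced TR1 array), and with medians of 0.10 in SK-Mel-28 and -0.28 in LOX. Without the SK-Mel-28 uninduced control array CXCL1 was at -0.92, CXCL2 at -0.44 and MVK at 0.655, and without the LOX one CXCL1 was at -3.60 and CXCL2 at -1.98. TP53INP1 was at 0.80 without the LOX uninduced TR1 array. Median centring put TYMS at 0.63, E2F2 at 0.50, NDUFB8 at -0.12 and RPS27L at -0.13, and E2F2 was at 0.14 with the mean of all probes.

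For single genes in uninduced cells, 3 of 19555 passed in limma, all lower and all of them probes without a genome position. MREG (-0.88 ± 0.0943 SE, adjusted p 0.0534) and TXNRD1 came next. The genes named by rank that missed the threshold (adjusted p 0.741 to 0.899) were LPCAT2 (0.62), SCD, MYO1D (0.61), MGAM (0.61) and the interferon-induced MX2 (0.67, 1 other probe opposite) on the higher side. On the lower side they were NAMPT, the rate-limiting enzyme of NAD salvage (-0.72), ZDHHC11 (-0.65) and the matrix proteoglycan BCAN (-1.08). With the mean of all probes MX2 was at 0.32 and BCAN at -0.59. MX2 was at 1.005 with the processed signals or the deposited table, and MGAM at 0.39 with Cy5 alone and 1.06 with a normexp offset of 0. At an unadjusted p under 0.05 there were 525 genes higher and 491 lower, 5.20% of the genes tested. That is near the 0.05 share that no change at all would give. Across genes the lines had a Pearson r of -0.02 and a Spearman rho of -0.12. The count of 3 ran from 0 (normexp offset of 0, no line block, or probes bright on all 8 arrays) to 12 (Cy5 alone), was 0 without the SK-Mel-28 uninduced TR1 or the LOX uninduced control array, and 1 without the SK-Mel-28 uninduced control array or the induced control array of either line. It was 5 without the LOX uninduced TR1 array and 7 without the induced TR1 array of either line, and among the lists the calls of cell cycle, cholesterol, p53 and oxidative phosphorylation ended or turned without the LOX uninduced control array (2 lists passed, adjusted p 0.00312 to 0.982), with medians of -0.15 for cholesterol, 0.05 for p53 and -0.04 for oxidative phosphorylation. Those of cholesterol, p53 and oxidative phosphorylation ended without the LOX uninduced TR1 array (0.103 to 0.738; p53 median -0.00582, oxidative phosphorylation -0.04). The NF-kB call ended without the SK-Mel-28 uninduced TR1 array (median -0.20, adjusted p 0.162), and oxidative phosphorylation also without the SK-Mel-28 uninduced control array (0.0882) or either induced TR1 array (0.0532). The p53 median was -0.22 without either the SK-Mel-28 uninduced TR1 or the SK-Mel-28 uninduced control array, and the cholesterol median 0.43 without the latter.

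Tetracycline with the control miRNA served as the measure of the drug and of miRNA expression itself. Cholesterol synthesis genes fell as a list (median -0.43, 11 of 29 lower and none higher in both lines, adjusted p = 1.43e-12, 0.659 with an estimated correlation), with a median of -0.87 in SK-Mel-28 and 0.02 in LOX. The sterol-pathway enzyme HSD17B7 was at -1.63 in SK-Mel-28 and -0.10 in LOX, and the mevalonate decarboxylase MVD at -1.16 and -0.27. Cytosolic ribosomal proteins fell (median -0.12, 25 of 35 lower in both lines, adjusted p = 5.88e-06, 0.659 with an estimated correlation; RPL18 -0.30, RPS25 -0.29). Oxidative phosphorylation, the mitochondrial respiratory chain, fell too (median -0.06, 22 of 46 lower in both lines, adjusted p = 0.00820, 0.659 with an estimated correlation), with ATP5F1B and UQCRB both at -0.24. Without the SK-Mel-28 uninduced control array HSD17B7 was at -0.21, MVD at -0.27 and ATP5F1B at -0.03, and without the LOX one at -1.525, -1.16 and -0.45. RPS25 was at -0.12 without the SK-Mel-28 and -0.46 without the LOX induced control array, and RPL18 at -0.10 with Cy5 alone. The mitochondrial ribosome list had a median of -0.03 (adjusted p = 0.381), and NRF2 targets had a median of 0.000722 (adjusted p = 0.965).

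No single gene passed for tetracycline in control miRNA cells: limma called 0 of 19555, with 856 (4.38%) at an unadjusted p under 0.05. The genes named by rank had adjusted p values of 0.863 and 0.908. Those on the higher side were CROCCP3 (0.74), the histone chaperone gene HIRA (0.88), JAKMIP3 (0.95), DGKI (0.62) and SERPINB2 (0.75). Those on the lower side were AAR2 (-0.58), ASB3 (-0.77), ZHX1 (-0.58), ACAP2 (-0.83) and CDC42SE2 (-0.67, 3 other probes opposite; -0.11 with the mean of all probes). With the processed signals or the deposited table CROCCP3 was at 2.07 and JAKMIP3 at 3.02. Without the SK-Mel-28 uninduced control array JAKMIP3 was at 0.47 and DGKI and SERPINB2 at 0.34. SERPINB2 was at 1.16 without the LOX uninduced and HIRA at 0.56 without the LOX induced control array. AAR2, ASB3, ACAP2 and CDC42SE2 were also among the genes on the higher side of the main comparison, which shares the induced control arrays. The SDs of log2 differences over genes were 0.244 in SK-Mel-28 and 0.137 in LOX, with a Pearson r across genes of 0.09 and a Spearman rho of 0.08. The list calls ended for cholesterol synthesis without the SK-Mel-28 uninduced control array (median -0.07, adjusted p 0.294). The cholesterol median was -0.16 without the SK-Mel-28 induced and -0.82 without the LOX uninduced control array. They ended for oxidative phosphorylation and ribosomal proteins without the SK-Mel-28 induced control array (0.0674 and 0.108; ribosomal median -0.06), and for oxidative phosphorylation without the LOX uninduced control array (0.172). Without the LOX induced control array 11 lists passed (ribosomal median -0.21), and 5 without either induced TR1 array or with the mean of all probes.

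Induction of the TR1 miRNA by tetracycline, set against the same cells without it, came with higher levels of NRF2 targets in both lines. The list rose with a median of 0.29 (27 of 32 members higher and 1 lower in both lines, adjusted p = 6.53e-26, 0.0729 with an estimated correlation), with medians of 0.32 in SK-Mel-28 and 0.22 in LOX. Adjusted over the list alone, 5 members passed: NQO1 (0.81 ± 0.103 SE, 1.75-fold), SLC7A11 (1.19 ± 0.207, 2.28-fold), GCLM, the modifier subunit of the glutathione-making enzyme (0.59 ± 0.125), GSR (0.44) and the pentose phosphate enzyme TALDO1 (0.33). None passed over all genes. Antioxidant enzymes outside the thioredoxin and glutathione systems rose as a list of 10 that shares NQO1, FTH1 and BLVRB with the NRF2 list (median 0.06, adjusted p = 0.00678, 0.557 with an estimated correlation), where the ferritin heavy chain gene FTH1 was at 0.41. Cholesterol synthesis genes fell (median -0.14, 24 of 29 lower and none higher in both lines, adjusted p = 0.000296, 0.768 with an estimated correlation), with SCD at -0.27 and LSS at -0.23, for each of which 1 of 3 other probes had the opposite sign.

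Single genes did not pass in this comparison in limma (0 of 19555, with 268, or 1.37%, at an unadjusted p under 0.05). TRIM16L (1.12 ± 0.117, 2.17-fold, adjusted p 0.132), NQO1 (0.266), SLC7A11 (1.00), KYNU, a tryptophan-degrading enzyme (0.82 ± 0.146, 1.00), and GCLM (1.00) were named by rank on the higher side and TXNRD1 on the lower. Across genes the lines had a Pearson r of 0.08 and a Spearman rho of 0.07. With the 4 TR1 miRNA arrays alone, an alternative added after seeing the data, 6 genes passed higher and 1 lower, among them TRIM16L, NQO1, SLC7A11, KYNU and TXNRD1. The calls of cholesterol synthesis and antioxidant enzymes ended without the SK-Mel-28 induced TR1 array (adjusted p 0.444 and 0.138, medians -0.06 and 0.03, with LSS at 0.00622, 5 lists passed and 1 gene called). SCD was at -0.11 with the mean of all probes, and without the LOX induced TR1 array SCD was at -0.41 and LSS at -0.46. The 2 list medians were -0.23 and 0.21 without that array, and without the SK-Mel-28 uninduced TR1 array the antioxidant median was 0.20. That of antioxidant enzymes also ended without the LOX uninduced TR1 array, while NRF2 targets passed without each of the 8 arrays. Only the 4 TR1 miRNA arrays enter this comparison, so leaving out a control miRNA array could alter the estimated spread but not the change.

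**Figure D4:**
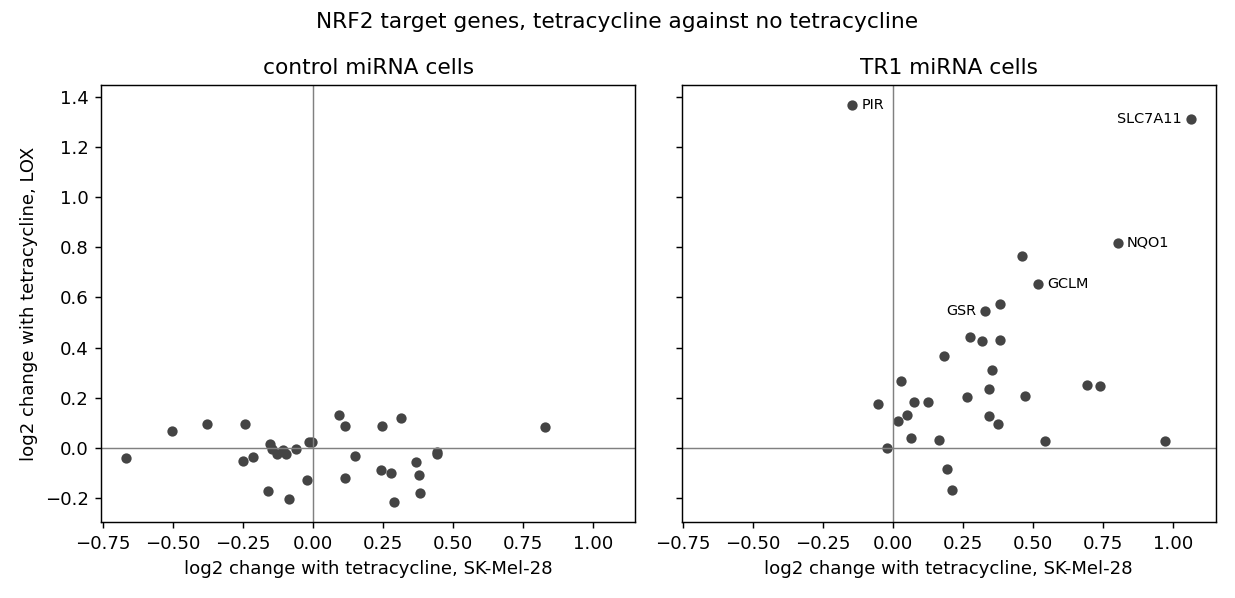
Log2 change with tetracycline of each measured NRF2 target gene in SK-Mel-28 (horizontal axis) and LOX (vertical axis), in control miRNA cells (left) and TR1 miRNA cells (right), 1 point per gene. In TR1 miRNA cells 27 of 32 genes lay above 0 in both lines, with SLC7A11 at 1.06 and 1.31 and NQO1 at 0.80 and 0.82.

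The change that tetracycline made in TR1 miRNA cells beyond that in control miRNA cells was tested as a difference of differences. NRF2 targets were higher by a median of 0.28 (24 of 32 higher and 1 lower in both lines, adjusted p = 2.24e-09, 0.316 with an estimated correlation), and NQO1 (0.88) and SLC7A11 (1.26) passed when adjusted over the list alone. Antioxidant enzymes (median 0.15, adjusted p = 0.0272, 0.566 with an estimated correlation; NQO2 0.32) were higher as well, as were the glutathione system (median 0.08, adjusted p = 0.0360, 0.566 with an estimated correlation; GSR 0.50, second probe opposite) and the pentose phosphate list (median 0.09, adjusted p = 0.0358, 0.798 with an estimated correlation; PGD 0.59). Cytosolic ribosomal proteins (median 0.11, adjusted p = 0.00127, 0.798 with an estimated correlation; RPL4 0.40, RPL18 0.33) and cholesterol synthesis (median 0.24, adjusted p = 0.00127, 0.798 with an estimated correlation; HSD17B7 0.83, MVD 0.62) were higher too, the latter with medians of 0.58 in SK-Mel-28 and -0.14 in LOX. Without the SK-Mel-28 uninduced control array NQO2 was at 0.13, PGD at 0.29, RPL4 at 0.08, HSD17B7 at 0.17 and MVD at 0.18, and without the LOX one at 0.51, 0.89, 0.73, 1.48 and 1.06. GSR was at 0.24 with the mean of all probes and RPL18 at 0.14 with Cy5 alone. In both the ribosomal and the cholesterol list the control miRNA cells had shown the fall with tetracycline given above.

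No single gene passed this test in limma (0 of 19555, with 517, or 2.64%, at an unadjusted p under 0.05, adjusted p of 1.00 for each named gene). TRIM16L (1.09), NQO1, AAR2 (0.68), DMRTC1 (0.67) and ZHX1 (0.66) were named by rank on the higher side, and TXNRD1, CROCCP3 (-0.74), EML1 (-0.69), AIF1L (-0.63) and LGI4 (-0.59) on the lower. With Cy5 alone DMRTC1 was at 0.19, AIF1L at -0.41 and LGI4 at -0.20. With the processed signals or the deposited table DMRTC1 was at 1.945, CROCCP3 at -2.18 and AIF1L at -1.56, and LGI4 was at -1.66 with a normexp offset of 0. Across genes the lines had a Pearson r of 0.12 and a Spearman rho of 0.11. Without the SK-Mel-28 induced control array 2 lists passed and 5 of the 6 calls ended (adjusted p 0.0542 to 0.840), all but that of NRF2 targets, with medians of 0.02 for glutathione and cholesterol and 0.04 for pentose phosphate and ribosomal proteins. Leaving out each of the other arrays ended 1 to 3 of the 5 calls other than NRF2 targets (0.0580 to 0.558 over these and the SK-Mel-28 uninduced control array), and 3 lists passed without the LOX uninduced TR1 array (glutathione median 0.05, ribosomal 0.04). Cholesterol medians were -0.05 without the SK-Mel-28 uninduced control, 0.61 without the LOX uninduced control, 0.54 without the LOX induced control and 0.37 without the SK-Mel-28 induced TR1 array. In the same order, ribosomal medians without the last 3 of these were 0.06, 0.22 and 0.06, with 0.17 without the SK-Mel-28 uninduced TR1 array. Pentose phosphate medians were 0.03, 0.23 and 0.18 without the first 3. Antioxidant medians were 0.31, 0.08, 0.29 and 0.07 without the 4, and 0.30 without either the SK-Mel-28 uninduced or the LOX induced TR1 array.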

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

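The comparison of list medians between the lines and the tests of explanations given here were chosen only after the results were seen, except the test of background correction and normalization. Of 145 pairs of a list and a comparison, 66 had medians of opposite sign in SK-Mel-28 and LOX, each from 1 array per line and condition. The 12 given here are those whose list passed its test or whose medians both lay outside the central 95% of random lists, a rule widened after the data were seen. None of these differences between the lines was tested. For metallothioneins, the SK-Mel-28 median minus the LOX median was -1.21 in the main comparison (-0.83 and 0.37), -1.23 between uninduced cells (-0.72 and 0.51) and 0.19 for tetracycline in TR1 miRNA cells (0.11 and -0.07). The metallothionein genes are near-identical paralogs, so probes of several members can read the same transcripts. For p53 targets it was 0.43 in the main comparison and 0.38 between uninduced cells. For cholesterol synthesis it was -0.54 between uninduced cells, -0.90 for tetracycline in control miRNA cells and 0.72 for the difference of the tetracycline changes. The interferon response gave -0.25 for tetracycline in control miRNA cells (-0.17 and 0.08), 0.20 in TR1 miRNA cells (0.08 and -0.12) and 0.45 for the difference of both (0.26 and -0.19). Keratinocyte markers gave 0.45 for tetracycline in control miRNA cells (0.30 and -0.15).

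The 7 probes without a human genome position were bright in the control miRNA cells of both lines and not well above background in TR1 miRNA cells. A tetracycline-inducible transcript of the control construct was set, after the result was seen, to need a median change over 1 (log2) in both lines. The medians with tetracycline fell short of that, at 0.48 in SK-Mel-28 and 0.32 in LOX. They were for the same 7 probes when chosen with no condition on the uninduced control arrays. That bound cannot decide on a transcript already made without tetracycline and raised further by it, which stays open. RNA of a bacterium with an AT-rich genome, such as a mycoplasma, may give such signals: the median GC content was 33.3%, below the lower quartile of 43.3% of 119 other bright probes without a position, yet the signal was not lower with tetracycline, an inhibitor of bacterial protein synthesis, a requirement added after the result was seen, without which the GC content alone would have gone with bacterial RNA. A construct transcript that does not depend on tetracycline also stays open, since the match of the 7 probes to the construct was not tested. These explanations cannot be told apart, and no biological explanation was tested for this signal.

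NRF2 targets were higher after induction of the TR1 miRNA in both lines. Tetracycline itself would act in control miRNA cells too, and the list's own p for the difference of the tetracycline changes was 0.0109 with an estimated correlation and 7.72e-11 with the preset one, although the former was 0.316 when adjusted over the lists. The signal of the probes without a genome position was absent from the range above background in the 4 TR1 miRNA arrays. Within these arrays the list's adjusted p was 9.67e-26 with the preset correlation in camera, while it did not pass with an estimated correlation (adjusted p 0.865) or with fry (0.133). The tetracycline comparison in TR1 miRNA cells already rests on the same 4 arrays, with the same median of 0.29. The fit of these arrays alone is therefore no separate check. Over the background, normalization and value-table alternatives the lowest median was 0.24 for tetracycline in TR1 miRNA cells and 0.20 in the induced comparison, both with Cy5 alone and above the bound of 0.1 set before the result was seen. A candidate hypothesis is that induction of the TR1 miRNA raised these genes, but between uninduced cells, with TXNRD1 at 31.04% and 46.6% of control, the list was not higher (median -0.05), and with a single TR1 miRNA, loss of TXNRD1 cannot be separated from other effects of that miRNA, which was not tested.

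Cholesterol synthesis genes were lower with tetracycline in SK-Mel-28 control miRNA cells. A brightness-dependent shift of that array would move random lists of the same size and brightness alike, and the list lay at percentile 0 of 10000 such lists. The list was picked for its low median, and loess had already adjusted each array for brightness. A low percentile was therefore likely from the start and decides little. A common effect of tetracycline on both lines is argued against as the whole cause by the median of 0.02 in LOX control miRNA cells, while a smaller one stays open, since the list was lower in TR1 miRNA cells of both lines (-0.19 in SK-Mel-28, -0.11 in LOX). The state of the single culture on that array could also give the pattern, as sterol genes respond to culture conditions. A second culture of the same line and condition is lacking, so this explanation and a response of this line cannot be told apart.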

How the results depend on the processing

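The fit of the 4 TR1 miRNA arrays alone was chosen only after the results were seen, and all other alternatives were fixed before the data were examined. For TXNRD1 and TXN, 175 alternative values kept their direction and their side of the threshold, 6 newly passed, 5 no longer passed and 6 turned sign. For the other genes named by rank or from a called list, 1852 were kept, 10 newly passed and 4 turned sign. For the lists called with the preset correlation, 428 were kept, 160 no longer passed and 3 turned sign. NRF2 targets in the induced comparison, with tetracycline in TR1 miRNA cells and in the difference of the tetracycline changes, and cholesterol synthesis in the induced comparison, passed in the same direction in 11 processing alternatives and without each of the 8 arrays, and did not pass with an estimated correlation or with fry. The cholesterol median of 0.41 there was 0.16 without the SK-Mel-28 induced control array and 0.62 without the LOX induced control array. That difference is no rise on induction within TR1 miRNA cells, where the cholesterol median with tetracycline was -0.14. Without an array, an arm holds 1 array, which is assumed to vary like the other groups. Leaving out an array of a condition outside a comparison alters the estimated spread but not the change itself. For the induced comparison and for tetracycline in TR1 miRNA cells, such leave-outs are therefore no check of the change. Signals near background limit the folds of dim probes. The causes of the changes given here were not tested.

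For the induced comparison, the count of 6 genes was 1 with the processed signals, 0 with a normexp offset of 0, 10 with Cy5 alone, 1 with the deposited table, 1 with probes bright on all 8 arrays, 2 without the replicate block and 0 to 6 without single arrays. For the uninduced comparison, the count of 3 was 1 with the processed signals, 0 with a normexp offset of 0, 12 with Cy5 alone, 1 with the deposited table, 6 with no filter on dim probes, 0 with probes bright on all 8 arrays, 0 without the replicate block, 6 with an intensity trend and 0 to 7 without single arrays. For tetracycline in TR1 miRNA cells, the count of 0 was 3 with Cy5 alone, 7 with the TR1 miRNA arrays alone and 0 to 1 without single arrays. The difference of the tetracycline changes gave 1 gene with Cy5 alone in place of 0. For tetracycline in control miRNA cells the count was 0 in every alternative run.

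TXNRD1 in the induced comparison was -3.65 with the processed signals (adjusted p 0.148), -3.24 with a normexp offset of 0 (0.0767), -3.65 with the deposited table (0.147) and -2.83 to -2.63 without single arrays, with adjusted p values of 0.000183 to 0.148 over the alternatives. In the uninduced comparison it was -1.39 and passed with no filter on dim probes (0.0256) and with an intensity trend (0.0385), and lay at -1.65 to -1.14 without single arrays (0.0222 to 0.583). With tetracycline in control miRNA cells TXNRD1 was -0.00533 with median centring, -0.00141 with Cy5 alone and -0.13 to 0.15 without single arrays. In TR1 miRNA cells it was -1.32 and passed with the TR1 miRNA arrays alone (0.0204). TXN was 0.13 with median centring in the uninduced comparison, and -0.257 to 0.0286 without single arrays for tetracycline in control miRNA cells.

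The count of lists called was 0 with an estimated correlation and 0 with fry in each of the 5 comparisons. Without single arrays it was 6 to 12 in the induced comparison (11 with all arrays), 2 to 7 in the uninduced (5), 2 to 11 for tetracycline in control miRNA cells (3), 3 to 11 in TR1 miRNA cells (3) and 2 to 8 for the difference (6). In the uninduced comparison it was 2 with the processed signals, 3 with a normexp offset of 0, 2 with the deposited table and 2 without the replicate block. It was 5 with the mean of all probes for tetracycline in control miRNA cells and 5 with the TR1 miRNA arrays alone in TR1 miRNA cells. For the difference it was 2 with the processed signals, 3 with a normexp offset of 0, 2 with Cy5 alone and 2 with the deposited table. Median centring turned the signs of oxidative phosphorylation (0.142) and NDUFB3 (0.0443) in the uninduced comparison, where it put the median of all genes at 0.109. Without single arrays, values there ran from -0.151 to 0.432 for cholesterol synthesis, from -0.00309 to 0.655 for MVK (both lowest without the LOX uninduced control array) and from -0.0830 to 0.800 for TP53INP1 (lowest without the SK-Mel-28 uninduced TR1 array). They ran from -0.0474 (without the SK-Mel-28 uninduced control array) to 0.612 for cholesterol synthesis in the difference. LSS with tetracycline in TR1 miRNA cells ran from -0.463 to 0.00622 (without the SK-Mel-28 induced TR1 array).

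The Pearson r between the lines, across genes, which are not independent, moved as follows. In the induced comparison (0.240) it was 0.195 with the processed signals, 0.192 with a normexp offset of 0, 0.325 with median centring, 0.289 with Cy5 alone, 0.193 with the deposited table, 0.176 with no filter on dim probes and 0.162 with probes bright on all 8 arrays. In the uninduced comparison (-0.0182) it was 0.0816 with the processed signals, 0.0138 with a normexp offset of 0, 0.0247 with median centring, 0.0816 with the deposited table and -0.139 with probes bright on all 8 arrays. For tetracycline in control miRNA cells (0.0938) it was 0.0672 with the processed signals, 0.0631 with a normexp offset of 0, 0.0674 with the deposited table, 0.0521 with no filter on dim probes and 0.0775 with the mean of all probes. For tetracycline in TR1 miRNA cells (0.0832) it was 0.0149 with the processed signals, 0.0218 with a normexp offset of 0, 0.0988 with median centring, 0.261 with Cy5 alone, 0.0130 with the deposited table, 0.0338 with no filter on dim probes and 0.108 with probes bright on all 8 arrays. For the difference (0.116) it was 0.0703 with the processed signals, 0.0698 with a normexp offset of 0, 0.157 with Cy5 alone, 0.0687 with the deposited table, 0.0645 with no filter on dim probes and 0.1003 with the mean of all probes.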

Other observations

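The comparison of levels between the lines was chosen only after the values were seen, and it has no test, since line, slide and reference RNA cannot be told apart. Of 24 tested melanocyte differentiation genes, 21 had a lower mean in LOX than in SK-Mel-28 over the 4 conditions, and 3 a higher one, MET (1.91), SNAI2 (0.27) and MC1R (0.22). In log2 Cy5 signal, the melanosome matrix protein gene PMEL differed by -9.17 (SD 0.173 over 4 conditions), the melanoma antigen gene MLANA by -8.60 (SD 0.161), the lineage transcription factor gene MITF by -5.82 (SD 0.366) and SOX10 by -4.98 (SD 0.123). Of 27 melanocyte differentiation genes on the array, 25 were well above background on the 4 SK-Mel-28 arrays and 19 on the 4 LOX arrays. The 19 include dim signals, with a mean log2 Cy5 in LOX of 6.58 for MLANA and 6.33 for SOX10. Genes of dedifferentiated or invasive melanoma went both ways, with the receptor kinase gene AXL at 4.46, but fibronectin (FN1) at -4.96 and TNC at -2.11. Among NRF2 targets, NQO1 lay at -1.83 (SD 0.127) and PIR at -6.94 (SD 0.620) in LOX relative to SK-Mel-28. Of the markers of other cell types, 6 of 18 keratinocyte genes were well above background on the 4 arrays of each line, as were 11 of 20 blood cell genes. Of 15 fibroblast genes 7 were in SK-Mel-28 and 9 in LOX, and of 12 endothelial genes 4 and 6. Counted per spot and array, 65.7% to 71.4% of all spots were well above background. These counts therefore do not by themselves show expression typical of such cells.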
